A study of Mus musculus with 768 samples.

How the data were processed

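Single dural macrophages were sorted by flow cytometry as Cd206_hi or Mhc2_hi cells and turned into Smart-Seq3 libraries, per the labels' protocols. The deposited files were a pair of tables of whole-number read counts per gene and cell, not normalized: a baseline table of 384 cells and 23534 genes, and an LCMV table of 295 cells and 21244 genes. STAR, featureCounts, Subread, Seurat 3.1.1 and the mm10 build were named in the submitters' processing notes, without roles or order. The gene annotation, the use of molecular identifiers, the strand setting and any filter on cells or genes before deposit are not given in the sources used here. Of the deposited non-zero counts, 78.5% in the baseline table and 73.8% in the LCMV table were even numbers, so they were treated as reads or read mates and not as molecules. The lowest total was 54 counts in the Cd206_hi baseline group and 3731 counts in the Cd206_hi LCMV group, so wells below the lowest LCMV total were in the baseline table only.

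Each column was matched to a labelled cell by its title. Of 768 labelled cells, 679 had a column and the others were not analysed here; 0 columns were left without a label, and 0 pairs of columns were identical. One labelled sample is 1 cell and no animal is named, so each of the 4 groups counted as 1 sample, cells were not taken as replicates, and no test, p-value or standard error was computed. Genes were limited to the 21244 in both tables; the other 2290 genes of the baseline table held 0.197% of its counts. Cells with at least 500 genes and at most 20% of counts on mitochondrial genes were kept, 507 in all: 131 Cd206_hi baseline, 168 Cd206_hi LCMV, 81 Mhc2_hi baseline and 127 Mhc2_hi LCMV cells, of 192 labelled in each group. Fewer than 500 genes removed 45 Cd206_hi and 106 Mhc2_hi baseline cells, the mitochondrial limit removed 16 and 5, and 0 LCMV cells were removed. No doublet caller was run, since each library comes from 1 sorted well; cells with markers of another type are given in its place.

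Counts of the kept cells were summed per group and expressed as CPM, counts scaled to a total of 1000000, computed here from the deposited counts. Log2 ratios used a pseudocount of 1 CPM, which makes the ratio of a low gene smaller. Genes entered the counts of 2-fold differences when the group with the higher level reached 20 CPM and had counts in 20% of its cells; list members needed 5 CPM. Intervals are exact 95% Poisson intervals of the summed counts and cover no more than counting error. They take each count as independent. Reads or read mates are not independent molecules, so the intervals are too narrow even for counting error. Reads of near-identical genes, such as Hspa1a and Hspa1b, the H2-Q genes, C4a and C4b, or the Cd209 lectins, could have been split or dropped by the counting, and values of these genes are uncertain for that reason.

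The comparisons were LCMV against baseline within each sort, Mhc2_hi against Cd206_hi within baseline and within LCMV, and the difference of the LCMV log2 ratios between the sorts. The groups, these comparisons, the summed measure, the thresholds, 14 kinds of alternative and the gene lists were fixed before the data were examined. There were 17 lists of programs and quality and 16 of cell type markers, 446 genes in all, of which 20 were not in both tables. The program and quality lists were interferon-stimulated genes, interferon-gamma responsive GTPases and partners, MHC class I and class II presentation, chemokines and cytokines, the CD206-high and MHC-II-high border macrophage signatures, complement and phagocytic receptors, virus sensing and interferon receptors, costimulatory and checkpoint ligands, inflammasome and cell death, alternative activation, iron and heme handling, cholesterol and lipid handling, glycolysis, cell cycle, and immediate early and dissociation response. Marker lists covered macrophages, monocytes, dendritic and plasmacytoid dendritic cells, neutrophils, T, NK, B, mast, erythroid, endothelial and mural cells, fibroblasts, osteoclasts, microglia, and Schwann cells with oligodendrocytes. A list was described by its median log2 ratio, the number of members at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of equal size matched on 10 bins of expression. The minimum of 4 measured genes for a median was set after seeing the data. Under an alternative the members were measured anew, and, as a choice added after seeing the data, also kept as in the summed counts, so that values of a list under different settings rest on the same genes. The medians of 1 list in different comparisons can rest on different genes.

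Named genes followed a rule: the sort markers Mrc1, H2-Aa, H2-Ab1 and Cd74; per comparison the 10 highest and 10 lowest log2 ratios past the floor that were also 2-fold in the same direction with cells weighted equally, leaving out predicted, mitochondrial, ribosomal, immunoglobulin, T cell receptor and sex-linked genes; per list up to 4 members with the largest absolute log2 ratio; and for the difference between the sorts the 6 most positive and 6 most negative. One gene that the rule takes is not reported here. Positions and identifiers came from GENCODE M21 on GRCm38, matched by symbol.

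Companion measures were chosen after seeing that a few deep cells held most counts: cells with at least 100000 counts weighted equally, and C1q cells, those that also had 1000 CPM of C1qa, C1qb and C1qc together (57, 104, 13 and 48 cells in the same order of groups). A rule of 3 markers of another type at 50 CPM was tried first, and the C1q minimum was then read from the spread of C1q levels. The 4 measures named with counts of genes are the sum, equal weight over all kept cells, deep cells and C1q cells. Values without the 1 cell that held the most counts of a gene, or moved a list's median most, were also chosen after seeing the data. To weigh depth, cells were thinned without replacement to 3700 counts, in 10 random draws whose mean is given; the cells deep enough numbered 104, 168, 59 and 127 in that order of groups.

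Alternatives covered equal weights, trimmed-mean scaling (30% of ratios and 5% of levels trimmed), totals without the 20 most abundant genes, pseudocounts of 0.1 and 10 CPM, a floor of 1 count or 100 CPM, all deposited cells, at least 1000 genes and at most 10% mitochondrial counts, thinning, leaving out cells marked as another type or the deepest 5%, and cells numbered 1 to 96 or 97 to 192. A cell was marked as another type when it had counts for at least 3 markers of that type and for a larger share of that list than of the macrophage list. This left out 2 Cd206_hi and 6 Mhc2_hi baseline cells and 0 LCMV cells. It is not the count of cells with 3 markers at 50 CPM, which takes no account of macrophage markers. The scripts were checked on simulated counts for 21244 genes with 200 changed by known amounts. With counting noise only, 100% of changed genes passed 2-fold. With spread added, 1 group of each contrast gave the profile and the spread between deep cells for both groups. That group was baseline in the LCMV contrasts and Cd206_hi in the sort contrasts. The spread and mix of cells in the other group were not simulated. True log2 changes of 2 then passed 2-fold in 87%, 83%, 93% and 95% of 100 genes. The order is the LCMV contrasts of Cd206_hi and Mhc2_hi cells, then the sort contrasts at baseline and with LCMV. True log2 changes of 1.5 passed in 82%, 82%, 65% and 81% of the other 100, and unchanged genes in 15.7%, 25.5%, 36.4% and 11.4%. Work was done in python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.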

Results

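Macrophages of the mouse dura mater, the outermost membrane around the brain, were sorted by flow cytometry into a Cd206_hi and an Mhc2_hi population, and each sorted cell gave its own Smart-Seq3 library, a plate-based method that reads along whole transcripts. CD206 is the mannose receptor encoded by Mrc1, and MHC class II is the molecule that presents antigen to helper T cells. Cells came from C57BL/6 mice at baseline (0 h) or from mice with lymphocytic choriomeningitis virus (LCMV), and the series asks how the macrophage subsets of the dura differ when a virus infects the whole animal. The time after infection is not given in the labels used here, so the LCMV values belong to an unknown time. The labels named 768 cells, in 4 groups of equal size, and no animals, so each group counted as 1 sample. Differences between groups therefore have no replicate check, and no test was made. Columns were analysed for 679 of them: every labelled baseline cell, and all labelled LCMV cells except 24 Cd206_hi and 65 Mhc2_hi cells.

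After filtering, 507 cells were kept. As shares of the cells with a column, these were 68.2% of the Cd206_hi and 42.2% of the Mhc2_hi baseline cells. For the LCMV cells of both sorts the share was 100%. Labelled LCMV cells without a column are not in that share, and the lowest totals lay in the baseline table only. Whether LCMV cells were filtered before deposit is not known. These shares, and the depths per cell given next, therefore compare unlike sets of cells. The kept cells summed to 152130001 counts in Cd206_hi baseline, 203310099 in Cd206_hi LCMV, 86174456 in Mhc2_hi baseline and 138377985 in Mhc2_hi LCMV. In the same order, the median kept cell held 49490, 467372, 12243 and 424263 counts and 2891, 4795, 2400 and 4932 genes. Counts were uneven between cells: the 5 deepest cells held 29.6% of the Cd206_hi baseline counts, 12.6% of the Cd206_hi LCMV counts, 69.8% of the Mhc2_hi baseline counts and 17.4% of the Mhc2_hi LCMV counts. Levels below are CPM, counts scaled to a total of 1000000, of the summed kept cells with exact 95% Poisson intervals. These intervals do not cover the spread between cells or animals. They take each count as independent, so for reads or read mates they are too narrow even for counting error. Beside the levels stand values in C1q cells, those with at least 100000 counts and 1000 CPM of C1qa, C1qb and C1qc together, each weighted equally. They were 57 of the 58 Cd206_hi and 13 of the 24 Mhc2_hi baseline cells of that depth, all but 1 of the Cd206_hi and 48 of the 69 Mhc2_hi LCMV cells, and they are a range of a continuous measure, not a cell type. For each gene list the median log2 ratio is followed by its value in C1q cells or by its range, the lowest and highest values over all settings tried, in each case over the same genes. Where 1 cell alone moved a median far or turned it, the value without that cell is given too. Single cells are named as in the labels, with 0h for baseline. Baseline and LCMV cells lie in separate tables, so infection and table differed together, while the 2 sorts were compared within a table.

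**Figure D1:**
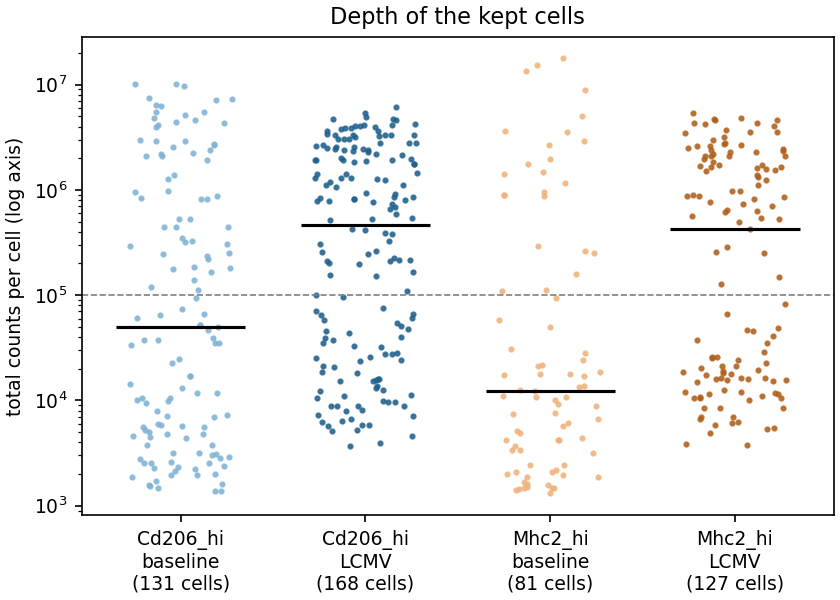
Total counts per kept cell (log axis) for the 4 groups; each point is 1 cell, the bar is the group median and the dashed line marks 100000 counts. Medians were 49490 and 12243 counts in the baseline groups and 467372 and 424263 in the LCMV groups.

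The sort markers followed the sorts in both tables. Mrc1 (chromosome 2, GRCm38) stood at 2876 CPM (2868 to 2885) in Cd206_hi baseline and 2582 CPM (2575 to 2589) in Cd206_hi LCMV cells, against 748 CPM (743 to 754) and 627 CPM (623 to 631) in the Mhc2_hi groups. H2-Ab1 (chromosome 17), which encodes a chain of MHC class II, stood at 329 CPM (326 to 332) and 180.9 CPM (179.1 to 182.8) in Cd206_hi cells against 20454 CPM (20423 to 20484) and 19256 CPM (19232 to 19279) in Mhc2_hi cells. Cd74, the invariant chain of MHC class II, had 1151 and 882 CPM in Cd206_hi cells and 36754 and 32625 CPM in Mhc2_hi cells, and H2-Aa had 292, 144.8, 14522 and 10544 CPM. The genes of the other sort were higher in shallow than in deep cells of both tables. The median level of H2-Ab1 in Cd206_hi LCMV cells was 5543 CPM in the 22 cells with 1000 to 10000 counts, and 36.9 CPM in cells with at least 1000000 counts. In Mhc2_hi LCMV cells the median level of Mrc1 was 1667 CPM in the shallowest range and 207 CPM in the deepest. At baseline these medians went from 439 to 16.2 CPM for H2-Ab1 in Cd206_hi cells and from 1113 to 10.1 CPM for Mrc1 in Mhc2_hi cells.

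**Figure D2:**
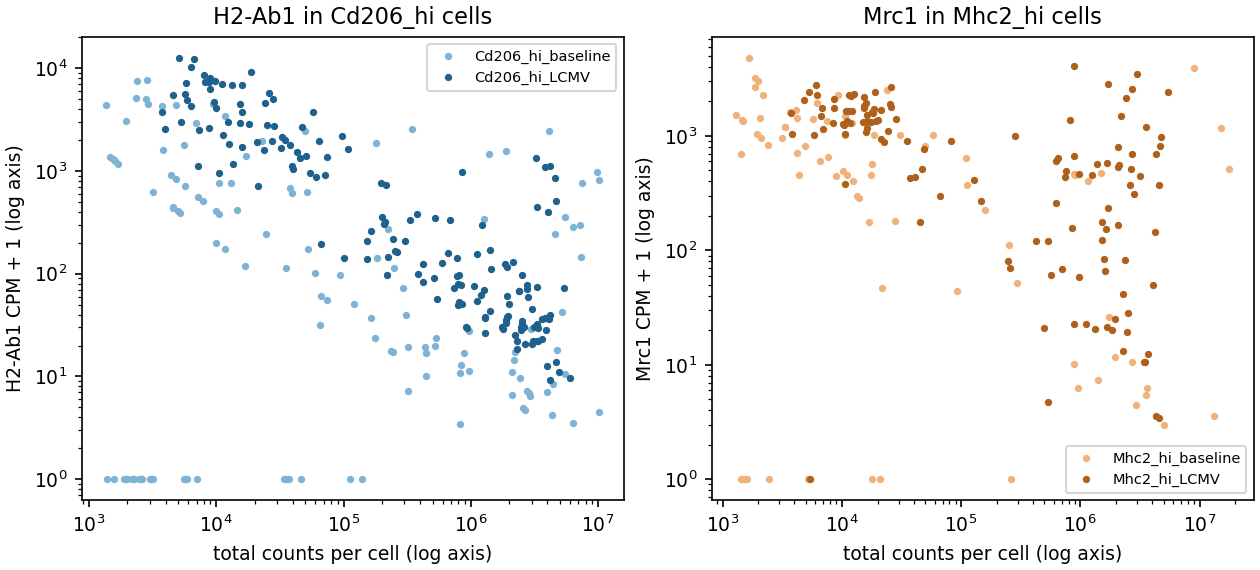
Level (CPM plus 1) of H2-Ab1 in Cd206_hi cells and of Mrc1 in Mhc2_hi cells against the total counts of the cell, both axes logarithmic; each point is 1 kept cell, coloured by baseline or LCMV. With LCMV the median of H2-Ab1 in Cd206_hi cells was 5543 CPM at 1000 to 10000 counts and 36.9 CPM at 1000000 counts or more.

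The first comparison set the sorts side by side at baseline. Most genes of MHC class II presentation were higher in Mhc2_hi cells, and most genes of the CD206-high border macrophage signature were lower. Of 11 measured genes of MHC class II presentation, 10 were at least 2-fold higher in Mhc2_hi cells and 0 lower, with a median log2 ratio of 4.996 (3.69 in C1q cells, range 3.17 to 6.15, 4.26 without cell Mhc2_hi_0h_51). Of 21 genes of the CD206-high border macrophage signature, 19 were at least 2-fold lower and 0 higher (median -2.64, -2.57 in C1q cells, range -5.25 to -1.86). Folr2, a folate receptor of resident macrophages, stood at 0.650 CPM (0.491 to 0.844) in Mhc2_hi and 169.6 CPM (167.5 to 171.7) in Cd206_hi cells, and Cd163, which takes up haemoglobin, at 8.78 CPM (8.17 to 9.43) and 794 CPM (789 to 798). The eosinophil chemoattractant Ccl24 had 0.696 CPM (0.531 to 0.896) against 348 CPM (345 to 351), a log2 ratio of -7.68. With all kept cells weighted equally the log2 ratios were smaller in size, -2.51 for Folr2, -1.86 for Cd163 and -3.22 for Ccl24.

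Iron and heme genes and alternative activation genes were mostly lower in baseline Mhc2_hi cells, while the number of lower complement genes and macrophage markers depended on how cells were weighted. Of 13 iron and heme genes, 8 were at least 2-fold lower and 0 higher (median -1.30, -0.90 in C1q cells, range -2.51 to -0.81, -1.90 without cell Mhc2_hi_0h_146), among them Slc40a1, the iron exporter ferroportin, at -5.59 (-1.10 in C1q cells). Of 8 alternative activation genes, 6 were lower and 0 higher (median -1.81, -1.65 in C1q cells, range -2.61 to -1.10). Of 24 complement and phagocytic receptor genes, 9 were lower, 1 higher and 14 within 2-fold in the summed counts (median -0.68, -0.67 in C1q cells, range -3.004 to -0.19). In cells with at least 100000 counts weighted equally, 16 of them were lower (median -1.26), and in C1q cells 10 were lower and 3 higher. Mertk, a receptor for apoptotic cells, was at -4.96 (-1.496 in C1q cells) and Stab1 at -4.02. Of 10 macrophage markers, 2 were lower, 0 higher and 8 within 2-fold in the summed counts (median -0.67, -0.40 in C1q cells, range -3.29 to -0.15), while 8 were lower in those deep cells weighted equally (median -1.25) and 2 in C1q cells. Csf1r, the receptor for the macrophage growth factor CSF1, was at -1.85. The MHC-II-high border macrophage signature, which shares 4 genes with the MHC class II list, was higher in 14 of 20 genes and lower in 0 (median 3.64, 2.96 in C1q cells, range 2.56 to 4.13, 2.87 without cell Mhc2_hi_0h_147). Il1b, an inflammatory cytokine in that signature, was at 4.68. MHC class I presentation had 7 of 20 genes higher and 1 lower (median 0.67, range 0.27 to 1.25), with H2-Q7, which has close copies such as H2-Q6, at 2.65.

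Markers of dendritic cells moved with the MHC class II genes. Of 9 dendritic markers, 7 were at least 2-fold higher in baseline Mhc2_hi cells and 1 lower (median 6.88, 3.96 in C1q cells, range 3.78 to 9.91), including Xcr1, a chemokine receptor of cross-presenting dendritic cells, at 178.3 CPM (175.5 to 181.1) against 0.0855 CPM (0.0455 to 0.146), Flt3 at 6.97 and Cd24a at 7.69. Of the 24 Mhc2_hi baseline cells with at least 100000 counts, 11 carried 3 or more dendritic markers at 50 CPM or more, and 10 of these 11 lay below the C1q minimum. The cells below the C1q minimum held 41.2% of the kept counts of this group. All 4 measured monocyte markers were higher (median 5.49, 4.03 in C1q cells, range 2.48 to 8.27, 4.79 without cell Mhc2_hi_0h_67), and Ly6c2, a surface protein of inflammatory monocytes, was at 6.26 and at 2.90 without that cell. B cell markers had a median of 5.07 (0.26 in C1q cells, range -0.0011 to 6.97), which was 0.16 without cell Mhc2_hi_0h_51, a cell with 99.8% of the Cd79a counts. Fibroblast markers had a median of -1.80 (-2.80 in C1q cells, range -5.05 to 1.37), which was -4.63 without cell Mhc2_hi_0h_145. Microglia markers had a median of -0.99 (range -2.78 to 0.046, 0.17 without cell Cd206_hi_0h_136). Plasmacytoid dendritic markers had one of -0.49 (range -0.98 to 0.21, -1.22 without cell Mhc2_hi_0h_66).

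Interferon genes at baseline depended on single cells. The interferon-stimulated genes had a median of 0.49 in Mhc2_hi against Cd206_hi cells (range -0.53 to 1.29), -0.27 without cell Mhc2_hi_0h_145 and -0.53 in C1q cells. For the interferon-gamma responsive GTPases and their partners the median was 1.67 (range -0.28 to 2.79), -1.77 without that cell and -0.28 in C1q cells, and that cell held 99.6% of the counts of Cxcl9, an interferon-gamma induced chemokine (8.63, 1.42 without it). Medians and ranges of further lists were -0.85 (-1.92 to 0.50) for chemokines and cytokines and 0.50 (0.22 to 1.52) for costimulatory and checkpoint ligands. They were, for virus sensing 0.12 (-0.34 to 0.60, -0.08 without cell Mhc2_hi_0h_147), inflammasome and cell death -0.04 (-0.39 to 0.41) and cholesterol and lipid handling -0.71 (-1.14 to 0.28). For glycolysis they were -0.01 (-0.27 to 0.48, 0.38 without cell Cd206_hi_0h_146), for the cell cycle -0.60 (-0.67 to 1.22, -1.24 without cell Mhc2_hi_0h_159) and for the immediate early and dissociation genes -0.69 (-1.39 to 0.73). Of 6179 genes past the expression floor, 967 were at least 2-fold higher and 1913 lower, and 298 and 560 were so in all 4 measures of level. Trimmed-mean scaling shifted the median of all genes by 0.48 and moved the share of higher genes among these from 33.6% to 56.6%. In simulated data with the spread between Cd206_hi cells given to both sorts, 36.4% of unchanged genes also passed 2-fold, so these counts describe size and are not calls.

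**Figure D3:**
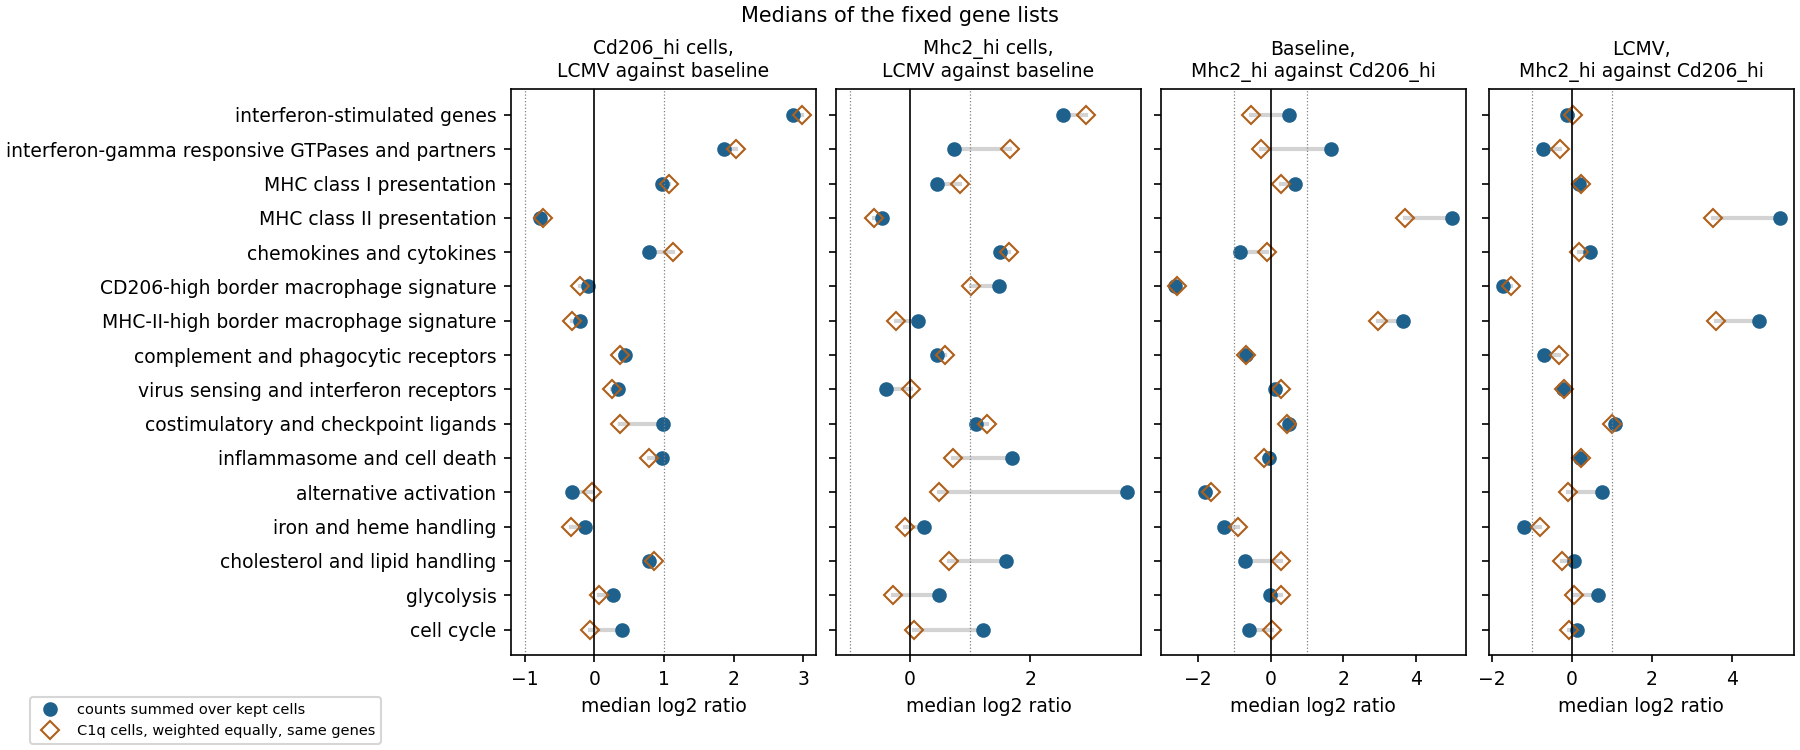
Median log2 ratio of 16 fixed gene lists (horizontal axis) in the 4 comparisons, 1 panel each; filled circles are summed counts of all kept cells, open diamonds the same genes in C1q cells weighted equally. The interferon-stimulated genes lay at 2.85 and 2.54 with LCMV in Cd206_hi and Mhc2_hi cells, and MHC class II presentation at 4.996 and 5.21 between the sorts.

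The next comparison asked what differed with LCMV in Cd206_hi cells. Interferon-stimulated genes, the antiviral set that type I interferon switches on, were higher in the LCMV cells almost throughout: 45 of 48 were at least 2-fold higher and 0 lower. Their median log2 ratio was 2.85, the 100th percentile of 10000 random lists of matched expression, and 2.98 in C1q cells. Ifit3 (chromosome 19), of the IFIT family of antiviral proteins, stood at 1811 CPM (1805 to 1816) with LCMV and 40.1 CPM (39.1 to 41.1) at baseline, and Oasl1 (chromosome 5), of the oligoadenylate synthetase family, at 511 CPM (508 to 514) and 2.248 CPM (2.016 to 2.499). Ifit1, Ifit2 and the antiviral GTPase Mx1 had log2 ratios of 6.17, 6.12 and 5.53, and 2.41, 2.75 and 2.45 with all kept cells weighted equally. The list's median lay between 2.08 and 3.94 under every alternative run, and was 3.42 without cell Cd206_hi_0h_163, the cell that moved it most.

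Gene groups next to the interferon response had some members higher and others within 2-fold. Of 17 interferon-gamma responsive GTPases and partners, 13 were at least 2-fold higher and 1 lower (median 1.86, 2.03 in C1q cells, range 1.64 to 3.88, 2.75 without cell Cd206_hi_0h_136), with Gbp4 at 5.39 and Iigp1 at 4.69, members of GTPase families that act on vacuoles holding microbes. MHC class I presentation had 9 of 20 genes higher and 1 lower (median 0.96, range 0.81 to 1.27), with the peptide transporter Tap1 at 1.78 and the proteasome activator Psme2 at 1.87. Of 22 measured chemokines and cytokines, 10 were higher and 0 lower (median 0.78, 1.12 in C1q cells, range 0.25 to 1.24). The monocyte chemoattractant Ccl12 stood at 5839 CPM (5829 to 5850) against 796 CPM (792 to 801), Ccl8 at 1262 CPM (1257 to 1267) against 97.9 CPM (96.3 to 99.4), and Cxcl10, which draws T cells, at 374 CPM (371 to 376) against 48.93 CPM (47.82 to 50.05). The inflammasome and cell death list was higher in 8 of 17 genes and lower in 0 (median 0.96, range 0.59 to 1.78), led by Ripk3 at 3.93 and the nucleic acid sensor Zbp1 at 3.84. Of 14 costimulatory and checkpoint ligands, 7 were higher and 1 lower (median 0.98, 0.36 in C1q cells, range 0.36 to 1.85, 1.58 without cell Cd206_hi_0h_165), including Tnfsf10, the death ligand TRAIL, at 4.49 and Cd274, the checkpoint ligand PD-L1, at 2.47. Virus sensing had 6 of 22 genes higher and 2 lower (median 0.34, range -0.54 to 0.50), with the RNA sensors Dhx58 at 3.64 and Ddx58 at 2.76. Dhx58, Ddx58 and Zbp1 are also in the interferon-stimulated list. That list shares 3 genes with virus sensing and 1 with inflammasome and cell death.

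Genes of macrophage identity were mostly within 2-fold between baseline and LCMV in Cd206_hi cells. In the CD206-high signature 5 of 22 genes were higher and 0 lower (median -0.09, range -0.21 to 0.11, 0.0066 without cell Cd206_hi_0h_164): Lyve1, a hyaluronan receptor of perivascular and border macrophages, stood at 717 CPM (713 to 721) against 126.1 CPM (124.4 to 127.9), the phosphatidylserine receptor Timd4 at 198 CPM (196 to 200) against 17.1 CPM (16.5 to 17.8), and complement C4b at 544 CPM (540 to 547) against 48.7 CPM (47.6 to 49.9). Complement and phagocytic receptors, which share 4 genes with that signature, were higher in 7 of 25 and lower in 0 (median 0.44, range 0.027 to 0.67), with Cfb at 3.82. MHC class II presentation had a median of -0.78 (-0.74 in C1q cells, range -1.06 to 0.60, -0.34 without cell Cd206_hi_0h_65). The MHC-II-high signature had one of -0.21 (-0.32 in C1q cells, range -0.34 to 0.93, 0.063 without cell Cd206_hi_0h_55). With all kept cells weighted equally they turned to 0.46 and 0.71, a weighting that includes the shallow LCMV cells, in which H2-Ab1 stood at a median of 5543 CPM. In deep cells the median of H2-Ab1 was also higher with LCMV. It was 140 against 18.5 CPM at 100000 to 1000000 counts, and 36.9 against 16.2 CPM in deeper cells. The summed level of those deeper cells went the other way, at 160 against 343 CPM. Cholesterol and lipid genes were higher in 6 of 17 and lower in 0 (median 0.78, range -0.088 to 1.16), with Ch25h, which makes the antiviral 25-hydroxycholesterol, at 1.62. Alternative activation had a median of -0.33 (range -0.35 to 0.49), iron and heme handling -0.14 (-0.34 to 0.021), glycolysis 0.27 (0.065 to 0.43) and the cell cycle 0.40 (-0.93 to 0.54).

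The immediate early and dissociation list had 7 of 21 genes at least 2-fold higher and 1 lower (median 0.64, range -0.49 to 1.48). Its member Hspa1b, an inducible heat shock protein with a near-identical copy in Hspa1a, stood at 274 CPM (272 to 276) with LCMV and 3.25 CPM (2.97 to 3.55) at baseline. All 7 fibroblast markers were lower with LCMV (median -4.75, -3.44 in C1q cells, range -6.04 to -3.44, -3.20 without cell Cd206_hi_0h_136). Col3a1, a fibrillar collagen, had 348 CPM (345 to 351) at baseline, 87.6% of it in that cell, and 1.38 CPM (1.23 to 1.55) with LCMV, and without that cell the log2 ratio was -4.31 in place of -7.20. All 6 endothelial markers were higher (median 3.61, 0.51 in C1q cells, range 0.029 to 6.44, 0.52 without cell Cd206_hi_32), and that cell held 99.3% of the counts of Aqp1, a water channel (6.94, 0.64 without it). Microglia markers had a median of -1.97 (range -2.64 to -1.05, -0.99997 without cell Cd206_hi_0h_136), osteoclast markers -1.21 (-1.89 to -0.091, -0.57 without that cell) and B cell markers -0.90 (-1.81 to -0.74). Dendritic markers had one of 0.91 (-0.84 to 1.19, -0.36 without cell Cd206_hi_38) and macrophage markers 0.57 (0.091 to 0.73). Of 6555 genes past the floor, 834 were at least 2-fold higher and 937 lower, and 417 and 420 were so in all 4 measures. Trimmed-mean scaling shifted the median of all genes by 0.16 and moved the share of higher genes from 47.1% to 58.5%, and 15.7% of simulated unchanged genes passed 2-fold.

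**Figure D4:**
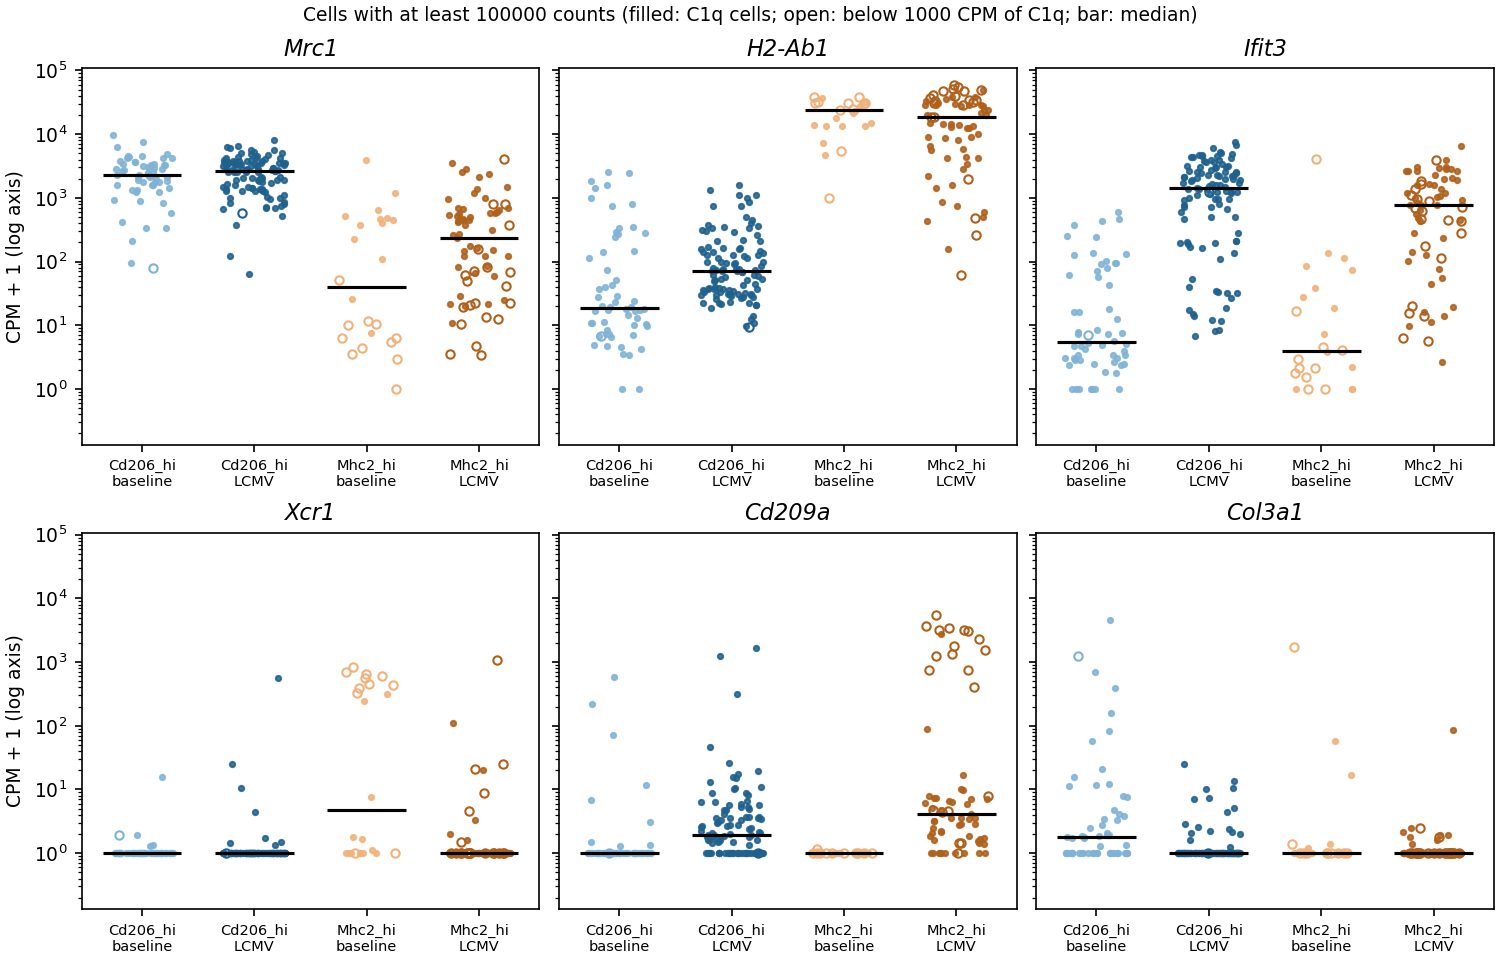
Level (CPM plus 1, log axis) of Mrc1, H2-Ab1, Ifit3, Xcr1, Cd209a and Col3a1 in cells with at least 100000 counts of the 4 groups; filled points are C1q cells, open points cells below 1000 CPM of C1q, and the bar is the group median. Summed over all kept cells, Ifit3 stood at 40.1 and 1811 CPM in Cd206_hi and at 135.5 and 1188 CPM in Mhc2_hi cells at baseline and with LCMV.

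The same contrast in Mhc2_hi cells again had the interferon-stimulated genes higher with LCMV. Of 48 such genes, 44 were at least 2-fold higher and 0 lower (median 2.54, 2.92 in C1q cells, 3.25 without cell Mhc2_hi_0h_145), and the median lay between 1.46 and 3.87 under every alternative run. Ifit3 stood at 1188 CPM (1182 to 1194) against 135.5 CPM (133.02 to 137.9), Oas3, which makes the messenger that activates RNase L, at 307 CPM (304 to 310) against 1.72 CPM (1.45 to 2.02), and Slfn4, a Schlafen family member, at 109.1 CPM (107.4 to 110.8) against 0.151 CPM (0.0803 to 0.258). Ifit3 was chosen here after its values were seen. With all kept cells weighted equally the log2 ratio of Oas3 was 1.53 in place of 6.83. Chemokines and cytokines were higher in 16 of 26 genes and lower in 1 (median 1.49, 1.65 in C1q cells, range 0.60 to 4.004, 2.12 without cell Mhc2_hi_0h_145), with the regulatory cytokines Il10 at 4.59 (0.41 with equal weighting) and Il27 at 4.40. Immediate early and dissociation genes were higher in 16 of 21 and lower in 0, and 9 were higher in C1q cells (median 1.53, 0.72 in C1q cells, range 0.36 to 2.07), with Hspa1b at 6.54.

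Of 22 genes of the CD206-high signature, 12 were at least 2-fold higher in Mhc2_hi cells with LCMV, 1 was lower and 9 lay within 2-fold (median 1.48, 1.01 in C1q cells, range 0.46 to 2.83). Mrc1, which names the other sort, was among the 9 in the summed counts, at 627 CPM with LCMV against 748 CPM. The median level of Mrc1 per cell was higher with LCMV in every range of depth. It was 207 against 10.1 CPM in cells with at least 1000000 counts, and 1667 against 1113 CPM in the shallowest range. The summed level of the deepest cells went the other way, at 625 against 781 CPM. Folr2 stood at 92.96 CPM (91.36 to 94.58) against 0.650 CPM, Cd163 at 200 CPM (198 to 202) against 8.78 CPM, and Cd209f, a C-type lectin, had a log2 ratio of 6.46, with 63.2% of its LCMV counts in cell Mhc2_hi_100 (5.05 without it). With all kept cells weighted equally, Folr2 had a log2 ratio of 1.63 in place of 5.83 and Cd163 of 0.06 in place of 4.36. The lectin Cd209a, a dendritic marker and a gene of the alternative activation list, stood at 573 CPM (569 to 577) against 0.0232 CPM (0.00281 to 0.0838). Its log2 ratio was 9.13 with the pseudocount, and the counting interval was 12.74 to 17.64 without it. The baseline level rested on very few counts, which that interval takes as independent. In C1q cells the log2 ratio of Cd209a was 5.95. Of 13 alternative activation genes, 8 were higher and 0 lower (median 3.61, 0.49 in C1q cells, range 0.49 to 4.70, 1.57 without cell Mhc2_hi_26). Il1rn, the interleukin 1 receptor antagonist, had a log2 ratio of 6.999 (1.68 in C1q cells). It is a secreted cytokine antagonist, although the fixed list of costimulatory and checkpoint ligands holds it. That list was higher in 7 of 14 genes and lower in 0 (median 1.10, range 0.88 to 2.70).

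Other groups in this contrast leaned on few cells, since the 5 deepest of the baseline cells held 69.8% of that group's counts. The interferon-gamma responsive list had 6 of 19 genes higher and 3 lower (median 0.73, range -0.83 to 2.48), and its median was 2.77 without cell Mhc2_hi_0h_145 and 1.67 in C1q cells. Inflammasome and cell death genes were higher in 9 of 17 and lower in 0 (median 1.69, 0.72 in C1q cells, range 0.60 to 1.72), with Mlkl, which perforates membranes in necroptosis, at 4.48. Cholesterol and lipid genes were higher in 11 of 18 and lower in 2 (median 1.59, 0.65 in C1q cells, range 0.65 to 1.95). Complement and phagocytic receptors were higher in 10 of 25 and lower in 0 (median 0.46, 0.58 in C1q cells, range 0.12 to 2.496, 1.09 without cell Mhc2_hi_0h_146), with Cfb at 3.56. MHC class I presentation had a median of 0.46 (range 0.058 to 0.83), MHC class II presentation -0.47 (-0.66 to -0.20), and the MHC-II-high signature 0.13 (-0.23 to 0.44, -0.15 without the same cell). The median was, for virus sensing, -0.40 (-0.60 to 1.46, 0.62 without cell Mhc2_hi_0h_147), and for iron and heme handling 0.24 (-0.080 to 1.03, -0.0015 without cell Mhc2_hi_0h_67). Glycolysis had one of 0.48 (-0.28 to 0.77) and the cell cycle 1.21 (-0.41 to 2.04).

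Most markers of dendritic cells were lower and most of those of monocytes higher in Mhc2_hi cells with LCMV. Of 10 dendritic markers, 7 were at least 2-fold lower and 3 higher (median -1.86, -1.78 in C1q cells, range -2.53 to -0.97, -0.94 without cell Mhc2_hi_0h_67), with Clec9a, a receptor for dead cells on cross-presenting dendritic cells, at -4.89. The dendritic median in C1q cells ranged from -1.89 to 0.43 with any 1 cell left out. Of 9 monocyte markers, 8 were higher and 1 lower (median 2.90, 1.13 in C1q cells, range 1.13 to 3.92, 3.72 without cell Mhc2_hi_0h_145), with Ly6c2 at 1180 CPM (1174 to 1186) against 77.6 CPM (75.8 to 79.5). All 8 B cell markers were lower (median -4.45, -0.46 in C1q cells, range -6.498 to 0.27), and the median was 0.03 without cell Mhc2_hi_0h_51. Fibroblast markers were lower in 6 of 7 and higher in 1 (median -3.80, -0.38 in C1q cells, range -4.95 to 0.89, -1.38 without cell Mhc2_hi_0h_145), and that cell held 97.9% of its group's counts of Dcn, a small matrix proteoglycan. Ptgds, a prostaglandin synthase, had a log2 ratio of -9.79, and -1.70 without cell Mhc2_hi_0h_68, which held 99.7% of its counts. Macrophage markers had a median of 0.39 (range -0.25 to 2.90), and microglia -0.81 (-1.47 to 1.97, -0.07 without cell Mhc2_hi_0h_150). The median was, for osteoclast markers, -0.29 (-0.67 to 1.57, 1.32 without cell Mhc2_hi_0h_145) and for plasmacytoid dendritic cells -0.49 (-1.66 to 1.81, 0.66 without cell Mhc2_hi_0h_51). Of 5947 genes past the floor, 1487 were at least 2-fold higher and 998 lower, and 376 and 228 were so in all 4 measures. Trimmed-mean scaling shifted the median of all genes by -0.19 and moved the share of higher genes from 59.8% to 50.2%, and 25.5% of simulated unchanged genes passed 2-fold.

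The sorts were then compared with LCMV. Interferon-stimulated genes stood at like levels in both: 1 of 48 was at least 2-fold higher in Mhc2_hi cells and 1 lower, with a median of -0.13 (range -0.13 to 0.02). Ifit1 had 453 CPM (450 to 457) in Mhc2_hi and 432 CPM (429 to 435) in Cd206_hi cells, and was chosen here after its values were seen. MHC class II presentation was higher in 10 of 11 genes of Mhc2_hi cells and lower in 0 (median 5.21, 3.54 in C1q cells, range 2.92 to 6.19), and the MHC-II-high signature in 17 of 21 and lower in 0 (median 4.69, 3.60 in C1q cells, range 2.37 to 4.94). The CD206-high signature was lower in 19 of 22 and higher in 1 (median -1.74, -1.52 in C1q cells, range -2.40 to -1.11), with Lyve1 at 48.4 CPM (47.2 to 49.5) against 717 CPM and complement C4b at 128.4 CPM (126.5 to 130.3) against 544 CPM. Cyr61, a matricellular protein, had a log2 ratio of -6.49 (-2.60 with all kept cells weighted equally).

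Genes of several immune functions differed between the sorts with LCMV. Costimulatory and checkpoint ligands were higher in 7 of 14 genes and lower in 1 (median 1.08, range 0.59 to 1.33), with the checkpoint receptor Havcr2, also called TIM-3, at 93.97 CPM (92.37 to 95.60) against 1.98 CPM (1.79 to 2.18). Chemokines and cytokines were higher in 11 of 26 and lower in 3 (median 0.45, range 0.06 to 0.96), with Ccl5, a T cell chemoattractant, at 6.02 and Il1b at 2692 CPM (2683 to 2701) against 47.5 CPM (46.6 to 48.5). The interferon-gamma responsive list was lower in 7 of 18 and higher in 2 (median -0.73, range -0.75 to -0.31), with Iigp1 at -2.14. Iron and heme genes were lower in 7 of 13 and higher in 0 (median -1.19, range -1.31 to -0.59), with Slc40a1 at 4.48 CPM (4.13 to 4.85) against 154.8 CPM (153.1 to 156.6). Complement and phagocytic receptors were lower in 7 of 25 and higher in 0 (median -0.71, range -0.90 to -0.32). Alternative activation had a median of 0.74 (range -0.09 to 0.88), glycolysis 0.64 (0.05 to 1.10) and MHC class I 0.19 (-0.01 to 0.32). Virus sensing had one of -0.22 (-0.24 to 0.27), inflammasome and cell death 0.19 (-0.01 to 0.41) and cholesterol and lipid handling 0.06 (-0.26 to 0.19, -0.10 without cell Mhc2_hi_28). The cell cycle had one of 0.12 (-0.08 to 1.16, -0.20 without cell Mhc2_hi_54) and immediate early genes 0.30 (0.037 to 0.95).

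Markers of monocytes and dendritic cells were higher in the Mhc2_hi sort with LCMV, beside its MHC class II genes. All 8 monocyte markers were at least 2-fold higher (median 5.31, 1.79 in C1q cells, range 1.79 to 6.43, 3.99 without cell Mhc2_hi_138), and Ly6c2 stood at 1180 CPM against 5.67 CPM (5.35 to 6.01). Fn1, the matrix protein fibronectin, had a log2 ratio of 7.37 (1.62 with all kept cells weighted equally, against 2.99 for Ly6c2). Of 9 dendritic markers, 7 were higher and 0 lower (median 3.64, 0.82 in C1q cells, range 0.82 to 5.38, 2.59 without cell Mhc2_hi_26), and 95.6% of the counts of Ccr7, which guides dendritic cells to lymph nodes, were in that cell (6.72, 2.36 without it and -0.44 in C1q cells). With any 1 cell left out, the dendritic median in C1q cells ranged from -0.42 to 1.70. Of 69 Mhc2_hi LCMV cells with at least 100000 counts, 11 carried 3 or more dendritic markers and 8 carried 3 or more monocyte markers at 50 CPM or more, against 0 and 0 of the Cd206_hi LCMV cells of that depth. Endothelial markers had a median of -2.83 (range -4.74 to 0.99, 0.23 without cell Cd206_hi_32), fibroblast -1.07 (-1.53 to 1.07) and microglia markers -1.34 (-1.81 to 1.19). For osteoclast markers it was 0.22 (-1.42 to 0.47, -0.94 without cell Mhc2_hi_100) and for macrophage markers -0.77 (-0.84 to -0.17). Of 6492 genes past the floor, 616 were at least 2-fold higher and 944 lower, and 262 and 299 were so in all 4 measures. Trimmed-mean scaling shifted the median of all genes by 0.13 and moved the share of higher genes from 39.5% to 49.97%, and 11.4% of simulated unchanged genes passed 2-fold.

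The LCMV contrasts of the sorts had genes in common. Among 5355 genes past both floors, 677 were at least 2-fold higher with LCMV in Cd206_hi and 1276 in Mhc2_hi cells, and 351 were shared. In the other direction 598 and 815 were lower, some of them in both. Genes that vary between cells, reads from other wells and the table difference could each put a gene in both contrasts, so these counts do not show a common response. Over the interferon-stimulated genes the median difference of the log2 ratios, Mhc2_hi minus Cd206_hi, was -0.39 (0.39 in C1q cells). The CD206-high signature had a median difference of 1.19 (1.01 in C1q cells), alternative activation 1.84 (0.67 in C1q cells) and the dendritic markers -2.32 (-2.03 in C1q cells). The dendritic median of the Mhc2_hi contrast in C1q cells, on which the last value rests, ranged from -1.89 to 0.43 with any 1 cell left out. Among genes the naming rule allows, the most positive difference was that of Ndnf at 9.0004 (5.28 without cell Cd206_hi_0h_136). The most negative was that of Ptgds at -12.07 (-3.98 without cell Mhc2_hi_0h_68). Without those cells neither would hold its rank against the values over all kept cells of Slc16a3 (7.25) and Rgs16 (-7.15). The value of Rgs16 also leaned on 1 cell, which was left in here, so Ptgds and Rgs16 were not treated alike. No test of any difference was possible with 1 sample per group.

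Lists with fewer than 4 measured genes gave no median. With LCMV in Cd206_hi cells, both measured monocyte markers, 1 of 2 mast cell markers and the 1 erythroid marker were at least 2-fold higher and none of these lower, and of 3 plasmacytoid dendritic and of 3 mural cell markers 1 was higher and 1 lower in each list. The 1 T cell marker lay within 2-fold. In Mhc2_hi cells the LCMV contrast had 2 of 3 endothelial markers higher and 1 lower, 1 of 2 mast cell markers higher and 0 lower, both T cell markers lower, and the 1 mural cell marker within 2-fold. At baseline, 1 of 2 mast cell markers was higher in Mhc2_hi cells and 0 lower, endothelial and T cell markers had 1 of 2 higher and 1 lower each, and both mural cell and 2 of 3 osteoclast markers were lower with 0 higher. With LCMV, 2 of 3 mast cell markers were higher in Mhc2_hi cells and 1 lower, 1 of 2 mural cell markers higher and 1 lower, and 2 of 3 plasmacytoid dendritic markers and the 1 T cell and 1 erythroid marker lower, while 0 of 3 B cell markers differed 2-fold. The 1 measured Schwann cell and oligodendrocyte marker, Mbp, lay within 2-fold in every comparison, and neutrophil and NK cell markers had 0 measured genes in all of them.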

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

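The tests of other cell types given here were chosen only after the results they bear on were seen, as were the thresholds that picked the genes and lists. With 1 sample per group, none of the differences was tested.

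Some genes stood on opposite sides of 0 in the LCMV contrasts of the sorts. The difference of log2 ratios, Mhc2_hi minus Cd206_hi, was 9.0004 for Ndnf (4.06 in Mhc2_hi and -4.94 in Cd206_hi cells; 5.28 without cell Cd206_hi_0h_136, and 1.14, from -0.98 to 2.53 over 10 draws, with cells thinned to 1 depth). It was 7.25 for the lactate transporter Slc16a3 (4.96 and -2.29), 6.56 for Siae (3.92 and -2.63) and 6.50 for Ttc32 (3.92 and -2.58). For the actin bundler Fscn1 it was 6.45 (4.59 and -1.85). Cell Mhc2_hi_26 held 88.3% of the Mhc2_hi LCMV counts of Fscn1, and without that cell the Mhc2_hi value was 1.62. For Phldb1 the difference was 6.32 (4.08 and -2.24), and 1.15, from -0.74 to 3.25 over 10 draws, with cells thinned to 1 depth. In the other direction it was -12.07 for Ptgds (-9.79 and 2.28; -3.98 without cell Mhc2_hi_0h_68), -7.15 for Rgs16 (-1.71 and 5.44; -2.25 without cell Cd206_hi_32), -7.03 for Xcr1 (-4.44 and 2.59; 0.038 in Cd206_hi cells without cell Cd206_hi_38), -6.14 for Cxcl9 (-4.40 and 1.74; 1.08 without cell Mhc2_hi_0h_145), -5.96 for Cep135 (-4.48 and 1.47; -2.25 without cell Mhc2_hi_0h_150) and -5.63 for Mpst (-2.14 and 3.49; -4.03 without cell Mhc2_hi_0h_146).

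List medians in the summed counts also lay on opposite sides of 0, but the side of the Cd206_hi medians depended on single cells or on the setting. The CD206-high signature had 1.48 in Mhc2_hi and -0.09 in Cd206_hi cells over the same 22 genes, a difference of the medians of 1.58 (median difference per gene 1.19). The Cd206_hi value was 0.0066 without cell Cd206_hi_0h_164. Alternative activation had 3.61 over 13 genes and -0.33 over 10, a difference of 3.94. Over the same 13 genes the Cd206_hi median was -0.03 and the median difference per gene 1.84. In cells 1 to 96 the -0.33 became 0.49, and in C1q cells the 3.61 became 0.49. The dendritic markers had -1.86 over 10 genes and 0.91 over 4, a difference of -2.78. Over the same 10 genes the Cd206_hi median was 0.46 and the median difference per gene -2.32. The 0.91 became -0.36 without cell Cd206_hi_38. Outside the compared genes, the genes found in the baseline table only held 0.197% of its counts.

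Markers of other cell types moved between the Mhc2_hi groups: B cell and fibroblast markers together had a median of -4.38 over 15 genes, dendritic markers -1.86 and monocyte markers 2.90 with LCMV, and dendritic markers were 3.64 higher in Mhc2_hi than in Cd206_hi LCMV cells. In C1q cells, which are chosen without use of these markers, the medians of the same genes were -0.38, -1.78, 1.13 and 0.82, and with any 1 cell left out they ranged from -0.70 to -0.33, -1.89 to 0.43, 1.03 to 1.49 and -0.42 to 1.70. The B cell and fibroblast pattern leaned on 1 cell each, both below the C1q minimum: without cell Mhc2_hi_0h_51, with 99.8% of the Cd79a counts, the B cell median was 0.03, and without cell Mhc2_hi_0h_145, with 97.9% of the Dcn counts, the fibroblast median was -1.38. These 2 cells may account for much of that pattern in Mhc2_hi cells, with Cd79a at 176.04 CPM and Dcn at 527 CPM in the group. In Cd206_hi cells all 7 fibroblast markers were also lower with LCMV (median -4.75, -3.44 in C1q cells). Of the deep Cd206_hi cells, 10.3% at baseline and 1.90% with LCMV carried 3 or more fibroblast markers at 50 CPM. A source of fibroblast reads common to both baseline groups was not tested and stays open. An Mhc2_hi gate would pass B cells, and whether it removed fibroblasts was not tested. These lists share 0 genes with other lists. Shares of deep Mhc2_hi cells with 3 or more dendritic markers at 50 CPM were 45.8% at baseline and 15.9% with LCMV. Below the C1q minimum lay 10 of these 11 cells at baseline and 11 of 11 with LCMV. For monocyte markers the shares were 4.17% and 11.6%. Cells are not replicates, so these shares were not tested. The dendritic and monocyte patterns stay open, since leaving out 1 cell moved the dendritic values past the bounds set for them and the monocyte values lay between the bounds. Whether LCMV itself altered the makeup of the dural Mhc2_hi cells was not tested.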

How the results depend on the processing

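The settings restricted to cells with at least 100000 counts, with or without the C1q minimum, were chosen after seeing the data; the others were fixed before. No paired analysis was possible because each group is 1 sample and the shared numbers only name cells. With 1 sample per group, leaving out replicates and other splits of the samples could not be run either. With list members measured anew in each setting, 27 of the 35 list medians at least 1 in size kept their direction in every setting that gave a value, and 562 of 578 values did, leaving out the interferon-stimulated and MHC class II medians given here. Over the members of the summed counts, a comparison added after seeing the data, 30 of 39 medians did with those included, and 644 of 663 values. Of the named gene values at least 1 in size over the comparisons, 7 turned in at least 1 setting, and 2506 of 2516 values kept their direction. Part of this was fixed in advance. A changed floor left every ratio and list median as it was, and a changed pseudocount cannot turn a gene's ratio between groups. Deep cells summed held nearly all counts, and genes named as highest or lowest had to be 2-fold the same way with equal weights. These counts therefore overstate how far the results were put to a test.
Values are given in the order Cd206_hi, then Mhc2_hi for the medians of interferon-stimulated genes (main 2.85 and 2.54), and baseline, then LCMV for the MHC class II medians between the sorts (4.996 and 5.21); the difference is that over interferon-stimulated genes (-0.39).

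With all kept cells weighted equally the interferon-stimulated medians were 2.08 and 1.46, the MHC class II medians 3.99 and 2.95 and the difference -0.71. Genes at least 2-fold higher with LCMV in Mhc2_hi cells numbered 896, and genes lower in the LCMV sort contrast 433. Turned in direction were H2-Aa with LCMV in Cd206_hi cells (0.93), the cell cycle with LCMV in Mhc2_hi cells (-0.48), and in the LCMV sort contrast fibroblast (3.63), endothelial (1.06) and microglia markers (1.19); over the members of the summed counts these were -0.34 for the cell cycle, 1.05 for fibroblast and 0.99 for endothelial markers. Thinned to 1 depth, as means over 10 draws, the medians were 2.36 and 1.83, and 4.24 and 2.92, and the difference -0.61. The genes higher and lower then numbered 334.1 and 193.3 with LCMV in Cd206_hi cells, 368.4 and 315.8 in Mhc2_hi cells, 391.7 and 460.3 between the sorts at baseline and 143.9 and 151.2 with LCMV. The same values turned, H2-Aa to 1.25, the cell cycle to -0.61, fibroblast to 3.38, endothelial to 1.21 and microglia to 1.16 (over those members -0.41, 1.07 and 0.74 for the cell cycle, fibroblast and endothelial markers). A mean over 10 draws replaced a single draw after seeing the data. The differences for Ndnf (-0.98 to 2.53) and Phldb1 (-0.74 to 3.25) turned in 2 draws each, and Il10 with LCMV in Mhc2_hi cells, fibroblast markers at baseline and Rgs16 in the LCMV sort contrast in 1 draw each. Thinning leaves fewer genes past the floor and weights cells equally; what turned these values was not tested beyond that.

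Trimmed-mean scaling gave 3.001 and 2.35, 5.46 and 5.34, and a difference of -0.73, with 1659 genes higher and 1271 lower between the sorts at baseline. Totals without the 20 most abundant genes gave 2.82 and 2.48, 5.09 and 5.36, and -0.44. A pseudocount of 0.1 CPM gave 2.86 for interferon-stimulated genes in Cd206_hi cells and 6.19 for MHC class II with LCMV. A pseudocount of 10 CPM, which shrinks ratios of low genes, gave 2.75 and 2.40, 3.17 and 3.13, and -0.34, with 575 genes lower in the LCMV sort contrast. With no floor beyond 1 count the genes higher and lower numbered 2308 and 3320, 4256 and 2862, 2534 and 5469, and 2207 and 2852 in the LCMV contrasts of Cd206_hi and Mhc2_hi cells and the sort contrasts at baseline and with LCMV. With a floor of 100 CPM they were 281 and 259, 434 and 400, 433 and 548, and 197 and 219. These counts follow the number of genes counted.

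With all deposited cells the genes lower with LCMV numbered 623 in Cd206_hi and 234 in Mhc2_hi cells, those higher in Mhc2_hi cells at baseline 313, and the interferon-stimulated median in Cd206_hi cells was 2.89. The stricter cell filter gave 2.83 for that median. Without the 2 Cd206_hi and 6 Mhc2_hi baseline cells marked as another type, a rule that left in every LCMV cell with dendritic or monocyte markers, the interferon-stimulated median in Mhc2_hi cells was 2.44 and the MHC class II median at baseline 4.39, and the B cell median at baseline turned to -1.09 over 4 genes (0.16 over the 8 of the summed counts, over which it turned to 0.026 with LCMV). Without the deepest 5% of cells the values were 3.29 and 1.88, 6.15 and 5.32, and -1.06, the fibroblast median at baseline turned to 1.37, and the endothelial median in the LCMV sort contrast, over the genes of the summed counts, to 0.31. For these settings the cause was not tested.

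Cells 1 to 96 gave 3.94 and 3.87, 5.24 and 5.33, and a difference of 0.35, with 1704 genes higher with LCMV in Cd206_hi cells. Turned were Bgn (0.093) and Cxcl12 (2.06) with LCMV in Mhc2_hi cells, the interferon-gamma responsive list at baseline (-0.30) the difference for Cxcl9 (2.94) and, over the genes of the summed counts, fibroblast markers with LCMV in Mhc2_hi cells (0.89). Cells numbered above 96 gave 2.67 and 2.16, 4.53 and 5.06, and -0.50, with 2047 genes lower with LCMV in Cd206_hi cells and 1485 higher in the LCMV sort contrast. Turned were H2-Aa with LCMV in Cd206_hi cells (0.50), B cell markers (-0.83) and Cd79a (-0.023) at baseline, microglia markers in the LCMV sort contrast (0.41) and the difference for Ptgds (0.65). Over the genes of the summed counts, B cell markers turned to 0.27 with LCMV in Mhc2_hi cells and -0.0011 at baseline, and endothelial markers in the LCMV sort contrast to 0.036. Single cells that fall in 1 of the 2 ranges of numbers, such as Mhc2_hi_0h_51, Mhc2_hi_0h_68 and Mhc2_hi_0h_145, hold most counts of B cell genes, Ptgds and Cxcl9, and the cause of the other moves was not tested.

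Deep cells summed gave MHC class II medians of 5.01 and 5.25, with 1498 genes lower with LCMV in Mhc2_hi cells. Deep cells weighted equally gave 3.12 and 2.51, 4.89 and 5.43, and -0.27, and the fibroblast median at baseline turned to 0.26 over 6 genes (-0.46 over the 7 of the summed counts) and the cell cycle with LCMV in Mhc2_hi cells, over those, to -0.015. C1q cells gave 2.98 and 2.92, 3.69 and 3.94 (3.54 over the genes of the summed counts), and a difference of 0.39. In them Cxcl12 with LCMV in Mhc2_hi cells (1.93), the interferon-gamma responsive list at baseline (-0.28) and Ccr7 in the LCMV sort contrast (-0.44) turned; the cause was not tested. The dendritic markers in that contrast were -0.53 over the 5 genes measured in C1q cells and 0.82 over the 9 of the summed counts, so this turn came with the change of genes. Depth limits the baseline groups most, where 24 Mhc2_hi cells with at least 100000 counts held 99.3% of the counts, so few cells stand behind each baseline value. A minimum of 2 measured genes for a list median, used before 4 was chosen, gave further turned values for short lists, which are not reported here.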

Other observations

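The test of reads from other wells and the test of depth were set before their results were seen, and the other tests given here were chosen only after the results were seen.

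Among the genes of the glycolysis list, Slc2a1 and Pfkp were higher in the Mhc2_hi sort in both tables, while 10 of its 17 genes at baseline and 13 with LCMV lay within 2-fold. Slc2a1, the glucose transporter GLUT1, had a log2 ratio of 2.67 against Cd206_hi cells at baseline (2.06 without cell Mhc2_hi_0h_67) and 2.74 with LCMV, and Pfkp, a platelet-type phosphofructokinase, 3.87 and 3.41, with 2.39 and 2.70 for Slc2a1 and 2.60 and 2.45 for Pfkp in C1q cells. The inhibitory receptor gene Havcr2 was likewise higher in both tables, at 3.05 (1.98 without cell Mhc2_hi_0h_67) and 4.995. Cyr61 was higher in Cd206_hi cells in both, with log2 ratios of -6.69 and -6.49 in Mhc2_hi cells.

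Some genes outside the interferon lists were also far higher with LCMV. In Cd206_hi cells Vsig4, a complement receptor of resident macrophages, stood at 67.89 CPM (66.76 to 69.03) against 0.546 CPM (0.435 to 0.676), a log2 ratio of 5.48 and 5.45 in C1q cells, and Ly6a, a surface protein induced by interferon, had a log2 ratio of 5.70. In Mhc2_hi cells Clec4e, which binds mycobacterial glycolipid, stood at 278 CPM (275 to 281) against 0.0232 CPM (0.00281 to 0.0838), with a counting interval of the log2 ratio of 11.70 to 16.60. That baseline level rested on very few counts, which the interval takes as independent. Between the sorts with LCMV, Mhc2_hi cells were higher in Tnip3 at 312 CPM (309 to 315) against 1.328 CPM (1.174 to 1.496) and in Tmem119, a gene often used to mark microglia, at 99.17 CPM (97.52 to 100.8) against 2.08 CPM (1.88 to 2.28).

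In shallow Cd206_hi LCMV cells, transcripts of the other sort were abundant, with H2-Ab1 at a median of 5543 CPM in the 22 cells under 10000 counts. A subset of cells positive for MHC class II, as the only source, would leave other shallow cells without it. At least 1000 CPM was found in 100% of the 22 cells, which argues against that. Reads from other wells could alone lift every cell past this level, so a subset beside them cannot be excluded. The excess over deep cells, as a share of the table's average level, lay within 2-fold of its median of 72.9% for 10 of 11 genes high in Mhc2_hi cells, or 90.9%. Reads from other wells of the same table may make up much of these shallow libraries. The test does not single them out. Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1 are among these genes and may vary together, and RNA of Mhc2_hi cells in the wells could give like shares. How such reads would have arisen was not tested.

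Interferon-stimulated genes were higher in the LCMV cells of both sorts. After thinning to 1 depth the smaller of the list medians was 1.83, and in C1q cells it was 2.92. These values argue against depth and against cells below 1000 CPM of C1q as the whole cause. The size of the difference still varied with depth for Ifit3. From 1000 to 10000 counts up to at least 1000000, its summed baseline level went from 381 to 34.9 CPM in Cd206_hi cells. In Mhc2_hi cells it went from 586 to 140.9 CPM. With LCMV these levels were 1652 and 1811 CPM in Cd206_hi cells, and 1350 and 1208 CPM in Mhc2_hi cells. In C1q cells the interferon-stimulated medians exceeded those of the immediate early and dissociation genes by at least 2.20. This argues against a handling response that moves both lists alike as the whole cause. In the summed counts of Mhc2_hi cells these 2 medians lay nearer to each other, at 2.54 and 1.53. Baseline and LCMV cells shared 0 tables, so a table or plate effect cannot be told apart from infection. A response to the virus may be the source and stays a hypothesis.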
